A study of Rattus norvegicus with 36 samples.

How the data were processed

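Lung RNA was sequenced from rats of a Sprague Dawley background that, per the labels, carried the human form of Slc39a12 (the gene of the zinc importer ZIP12) in place of the rat gene. Adult animals of 200 to 240 g were kept in normoxia or breathed 10% oxygen at normal pressure for 2 weeks. Hypoxic animals received the anti-ZIP12 antibody APL-9796 or control IgG at 10 mg/kg by intraperitoneal injection, with dosing begun 48 h before hypoxia and repeated every 3 days. Sample labels gave the sex and arm of each of the 36 libraries: 6 males and 6 females in normoxia, in hypoxia with IgG, and in hypoxia with APL-9796. The labels of the normoxic libraries name no antibody, so hypoxia and IgG cannot be told apart in the comparison of those arms. The labels describe rats allocated to groups but do not state that each library came from a separate animal; p-values measure the spread between these libraries.

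The deposited table held whole-number read counts per gene, without normalization, and a deposited information sheet held other descriptors of each library, among them its library pool and flow cell. Arm and sex in that sheet matched the sample labels in 36 of 36 libraries. Of the authors' processing, DESeq2 1.24.0 is named in the submitters' processing notes; the aligner, counting tool, strand setting and genome build are not given in the sources used here. Without the strand setting, reads of overlapping and antisense genes cannot be separated, and reads of near-identical gene copies, such as olfactory receptors, may be split among them. The table named 27308 genes plus 1 line of totals, which held 0.0% of the gene counts used here and stayed out of library sizes and tests. Gene identifiers were those of the table. Names given there were brought to current symbols with a RefSeq gene table of the rat assembly GRCr8, used for names and not for coordinates: 11611 genes with 68.9% of counts had a current symbol, 7447 directly and 3666 through an older symbol. The other 15697 genes were tested without a name.

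Total counts ran from 6.07 to 20.8 M per library, with a median of 11.1 M. A count of 0 was read as an upper limit of 3 counts of the total, which covers counting error only, as do exact 95% intervals on ratios of pooled counts. Levels are CPM (counts relative to the library total), computed here from the counts with TMM-scaled library sizes and given as mean ± SD over libraries. Changes were tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, robust quasi-likelihood test) in 1 model of all 36 libraries with a term for each of the 6 groups. This left 15570 genes, of which 6193 had no symbol. Contrasts over both sexes weighted males and females equally. Log2 fold changes are given ± SE, and FDR stands for the Benjamini-Hochberg adjusted p of that test, with a threshold of 0.05. Gene lists for pathways and cell types, 45 of which had members to test, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all in the same model and adjusted over the lists of a contrast. Camera compares a list with the other genes, whereas fry asks whether its genes move on balance 1 way, or in either direction, without that comparison. Principal components used log2 CPM (prior count 2) of the 1000 genes with the highest variance. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

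Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. For hypoxia and for APL-9796 against IgG, the rule took the 10 largest rises and the 10 largest falls among genes past the threshold that had a symbol, a mean of at least 1 CPM and the same direction in both sexes. For each of the other 8 contrasts it took the 5 smallest p-values on the same conditions, without that on direction for single-sex and interaction contrasts, and where no gene passed it took the 5 smallest p-values. It added up to 4 members with the smallest p-values from each list called by camera and from 7 lists fixed for this question, and Slc39a12 in every case. Other genes are named as chosen after their values were seen. The result of 1 list called for hypoxia is not reported here.

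Alternatives were RLE size factors, no filter on low counts, a filter at 1 CPM in 12 libraries, DESeq2 1.42.0, limma-voom with quality weights (limma 3.58.1), a model of the compared groups alone, a replicate block, 1 surrogate variable (sva 3.50.0), a test against a 1.2-fold change (glmTreat) and leaving out each library in turn. Chosen after seeing the data were the sequencing run (pool and flow cell, with 3 runs of 26, 9 and 1 libraries, called A, B and C) as a term, run A alone, and 3 sets of libraries left out. Runs were uneven between groups. Run A held 5 male and 2 female IgG libraries, 5 male and 5 female APL-9796 libraries, and 6 male and 3 female normoxic libraries. Counts in run A alone therefore rest on fewer libraries. For single genes, ranges over the alternatives cover these settings, except glmTreat, and leaving out each library in turn. For lists, camera was run again in 4 of them only, with the run as a term and with each set of libraries left out, and ranges for lists cover those 4. The model was tested on simulated data drawn from the real means and library sizes with 200 changed genes per contrast. Changed genes had a mean of at least 1 CPM, genes varied independently and no library stood apart, so recovery in the real data may be lower. At 1.25-, 1.5- and 2-fold it recovered 28.5%, 74.5% and 94.5% for APL-9796 against IgG, and 32.5%, 79.5% and 95.0% for hypoxia.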

Results

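Lung transcriptomes of rats with a humanised Slc39a12 gene were measured in 36 RNA sequencing libraries, 12 per arm and 6 per sex in each arm. The series concerns ZIP12 zinc signalling as a target in pulmonary hypertension, for which 2 weeks of hypoxia is the model. Totals ran from 6.07 to 20.8 M counts, and the median total of a group ran from 9.11 M in females with hypoxia and IgG to 12.5 M in females with hypoxia and APL-9796. Pairs of libraries within a group had Spearman correlations across genes of 0.937 to 0.995, and no pair agreed within sampling noise (lowest chi-square per gene 3.86). The deposited entry for Slc39a12 (rCG_55714) had 0 counts in all 36 libraries, which allows up to 0.144 to 0.494 CPM per library, or 0.00735 CPM over the pooled counts. Whether reads of the human gene would be counted there is not given in the sources used here, so the target itself was not measured. Of 6 sex-linked genes fixed to check the labels, 0 had a row. An unnamed gene (rCG_38070) separated the sexes as labelled in 36 of 36 libraries, with 238 CPM or more in females and 5.44 CPM or less in males. Its link to sex is known only from these libraries, so it is not an independent check of the labels. The 5.44 CPM (65 counts) was that of male APL-9796 5, and the other males had at most 0.522 CPM.

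Normoxic and hypoxic libraries parted along the first principal component, which held 20.7% of the variance. Its mean was 14.3 ± 10.9 in normoxia, −7.07 ± 7.73 in hypoxia with IgG and −7.19 ± 7.71 in hypoxia with APL-9796 (SD, n = 12 each). The normoxic libraries spanned 3.16 to 44.3, with female normoxia 9 at 44.3. The highest hypoxic library lay at 4.97.

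**Figure D1:**
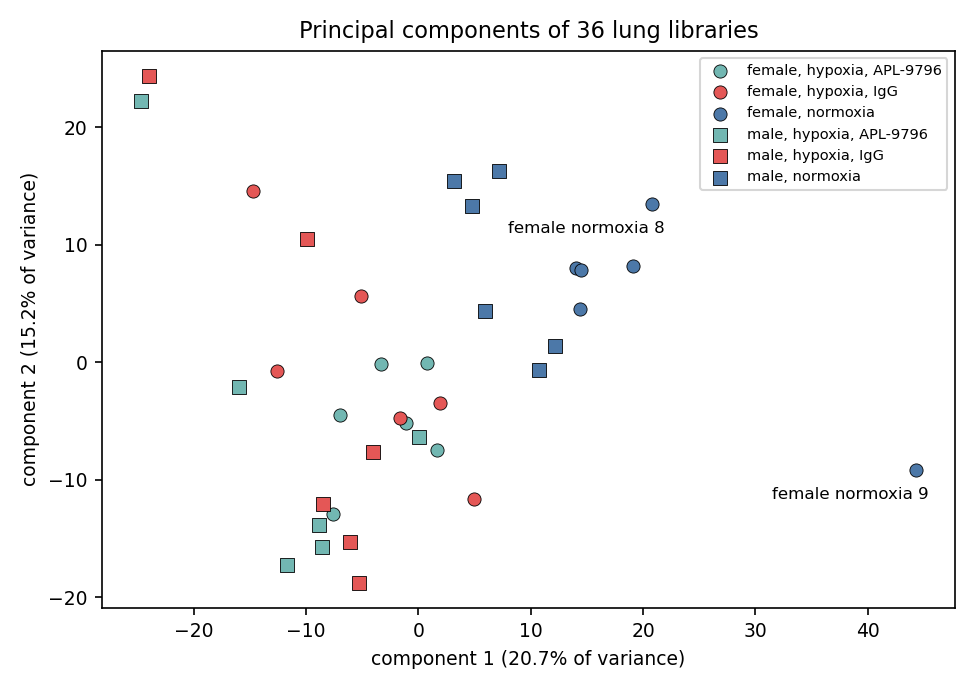
First and second principal component of log2 CPM (20.7% and 15.2% of the variance) for the 36 lung libraries, 1 point per library, by arm and sex. Normoxic libraries average 14.3 on the first axis, against −7.07 with IgG and −7.19 with APL-9796, whose points intermingle.

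The first question is what hypoxia with IgG changed against normoxia. Of 13 smooth muscle contractile genes 9 rose and of 27 extracellular matrix genes 17 rose, with 0 lower in either list, and of 17 endothelial markers 7 rose and 5 fell. The first and second list were called by camera (FDR = 6.0e-10 and 3.4e-13) but not with an estimated correlation (adjusted p = 0.129 and 0.186). Myl9 (rCG_37420), a light chain of smooth muscle myosin, rose from 98.7 ± 20.8 to 180 ± 30.2 CPM (log2 0.88 ± 0.11, FDR = 1.5e-07). Col15a1 (rCG_54988), a basement membrane collagen, rose from 140 ± 42.4 to 331 ± 34.9 CPM (1.28 ± 0.10, FDR = 9.4e-12). The endothelial sialomucin Emcn (rCG_28624) rose from 140 ± 35.2 to 312 ± 54.8 CPM, whereas Edn1 (rCG_44111), the gene of the vasoconstrictor endothelin-1, fell from 159 ± 49.0 to 65.8 ± 14.4 CPM (−1.28 ± 0.14, FDR = 2.6e-08). The natriuretic peptide clearance receptor Npr3 (rCG_23642) fell from 112 ± 33.9 to 18.5 ± 8.08 CPM (all SD, n = 12). In total 983 genes were higher and 964 lower, of 15570, and 195 of these differed by more than 2-fold (143 higher, 52 lower). Of the 68 named genes past the threshold, 48 had all 12 IgG libraries on the side of the change against the normoxic mean of their sex, and 63 had at least 10. The genes were chosen in these same libraries, so these counts describe how even the changes were and give no separate support. The total of genes past the threshold was 725 in sequencing run A alone. That run kept 5 male and 2 female IgG libraries and 6 male and 3 female normoxic libraries. A loss of calls from fewer libraries was not told apart from an effect of run.

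The 10 largest rises included Slc1a6 (rCG_29419), a glutamate transporter, with 2 counts in 143 M over the normoxic libraries and 438 counts in the IgG libraries, a ratio of 227 (exact 95% counting interval 62.4 to 1877). Slc26a10, of the SLC26 anion transporter family, rose from 1.36 ± 0.815 to 26.6 ± 11.8 CPM (log2 4.37 ± 0.33, FDR = 9.4e-12). Mycn (rCG_62224), a transcription factor of growth control, rose from 1.76 ± 0.871 to 15.2 ± 5.53 CPM (3.08 ± 0.27, FDR = 1.2e-10). Fam181b (3.99), the secreted matrix protein Coch (3.30), Susd5 (2.53) and the olfactory receptor Olr59 (2.53), a member of a large multigene family, were higher in 12 of 12 IgG libraries. The remaining members of this set were not shared by all libraries. The brown fat uncoupling protein Ucp1 rose by 5.57 (FDR = 0.00375) and was higher in 8 of 12 libraries, the fat cell receptor Adrb3 rose by 3.16 in 9 of 12, and the circadian factor Dbp rose by 2.62 in 6 of 12. Without male IgG 6, female IgG 11 and male APL-9796 5, which had high summed levels of adipocyte, cardiac or skeletal muscle genes, Ucp1 stood at 2.84 (FDR = 0.123, 0.00222 to 0.284 over the alternatives) and Adrb3 at 1.72 (FDR = 0.0624, 8.2e-05 to 0.134). In run A alone Dbp stood at 1.75 (FDR = 0.321, 0.00029 to 0.321).

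The 10 largest falls were led by the nuclear receptor Nr5a2 (−2.82 ± 0.37), Npr3 (−2.61 ± 0.22) and the hyaluronan receptor Lyve1 (rCG_40332), which went from 420 ± 84.4 to 69.8 ± 27.9 CPM (−2.60 ± 0.20, FDR = 2.1e-11). Esm1 (rCG_44604), a proteoglycan secreted by endothelial cells, went from 102 ± 22.4 to 27 ± 4.78 CPM (−1.91 ± 0.12, FDR = 2.9e-14). The cannabinoid receptor Cnr1 (43.1 ± 16.4 to 14.8 ± 4.79 CPM), the collagen VI chain Col6a4 (log2 −1.42), Sybu (−1.39) and Stox1 (−1.34) were lower in 12 of 12 IgG libraries, and Apol2 (−1.46) and Mlc1 (−1.46) in 11 of 12. Mlc1 stood at −0.78 (FDR = 0.241, 0.0102 to 0.241 over the alternatives) without female normoxia 8 and 9, and also lost its call without male normoxia 3.

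Among the gene lists, 17 of 27 extracellular matrix genes rose and 0 fell (camera FDR = 3.4e-13, adjusted p = 0.186 with an estimated correlation). Adjusted over the list alone, 19 rose and 1 fell. Besides Col15a1 these included the cartilage matrix protein Comp, the latent TGF-beta binding protein Ltbp2 (308 ± 130 to 499 ± 100 CPM) and the lysyl oxidase Loxl2 (0.59). Of 13 smooth muscle genes 9 rose and 0 fell (camera FDR = 6.0e-10, adjusted p = 0.129 with an estimated correlation, 10 and 0 adjusted over the list alone). Among them were the calponin gene Cnn1 (0.82), the potassium channel subunit Kcnmb1 (0.74) and the smooth muscle actin Actg2 (0.57). Of 16 pericyte and fibroblast markers 6 rose and 1 fell, the same counts as adjusted over the list alone (camera FDR = 0.00426, adjusted p = 0.439 with an estimated correlation). Notch3, a receptor of mural cells, went from 145 ± 53.7 to 235 ± 45.7 CPM, Gli1 rose by 0.85 and Higd1b by 0.53, and Rgs5 fell by 0.56. In run A alone, 8 matrix, 6 smooth muscle and 2 pericyte and fibroblast genes rose.

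Of 17 pan-endothelial markers 7 rose and 5 fell (8 and 5 adjusted over the list alone), and the list was called higher (camera FDR = 0.0428, adjusted p = 0.549 with an estimated correlation). Without female normoxia 8 and 9 its FDR was 0.0576 (0.0123 to 0.0576 over 4 alternatives). The guidance receptor Robo4 rose by 0.97, the angiopoietin receptor Tek went from 673 ± 89.4 to 436 ± 65.1 CPM and the VEGF receptor Flt1 fell by 0.48. In the list of pulmonary hypertension risk and BMP/TGF-beta genes 9 of 33 rose and 3 fell (10 and 3 adjusted over the list alone), and the list was not called by camera (FDR = 0.0689), although it was with sequencing run as a term (FDR = 0.0422, 0.0422 to 0.218 over 4 alternatives, adjusted p = 0.451 with an estimated correlation in that setting). It was called higher by fry (adjusted p = 0.0108, 2.1e-19 for changes in either direction). The activin antagonist Fst went from 9.54 ± 2.72 to 26.4 ± 8.16 CPM, Tgfb3 rose by 0.64 and the receptor Tgfbr2 by 0.40, and the inhibitory Smad6 went from 258 ± 58.9 to 154 ± 19.6 CPM. Of 26 vasoactive genes 5 rose and 8 fell (7 and 8 adjusted over the list alone, camera FDR = 0.347), with a median log2 change of 0.11 and a mean of −0.09. By fry it was called for changes in either direction (adjusted p = 2.8e-22) but not for 1 direction (0.116). Besides Edn1 and Npr3, the angiotensin-converting enzyme Ace (rCG_33109) fell from 1916 ± 231 to 1265 ± 181 CPM (−0.60 ± 0.07, FDR = 9.6e-08), and the peptide ligand Apln fell by 0.84.

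Of 15 glycolysis genes 4 rose and 0 fell (6 and 0 adjusted over the list alone, camera FDR = 0.00217, adjusted p = 0.439 with an estimated correlation). These included the aldolase Aldoc (4.56 ± 0.923 to 10.0 ± 2.84 CPM), Pfkl (0.63) and Eno2 (0.49). Of 19 HIF target genes 4 rose and 1 fell (6 and 3 adjusted over the list alone), and the list was not called by camera (FDR = 0.247, median 0.09, mean −0.03). It was called higher by fry (adjusted p = 0.0369, 3.5e-10 for changes in either direction), opposite in sign to its mean. The kinases Pdk1 (0.45) and Pfkfb4 (0.28) rose, and the lipoprotein lipase inhibitor Angptl4 fell by 0.73. In run A alone 1 rose and 0 fell. Of 17 zinc transporters and metallothioneins 0 rose and 2 fell, also adjusted over the list alone. The list was not called by camera (FDR = 0.247) but was called lower by fry (adjusted p = 0.00952, 0.262 for changes in either direction). The zinc exporter Slc30a5 (rCG_44645) went from 91.2 ± 15.3 to 79.2 ± 5.59 CPM (log2 −0.20 ± 0.06, FDR = 0.0150) and the zinc importer Slc39a4 (rCG_60103) from 193 ± 26.1 to 163 ± 18.8 CPM (−0.24 ± 0.07, FDR = 0.0276). Without female normoxia 8 and 9 the zinc list had 1 gene higher and 0 lower, and in run A alone 0 and 0. Slc39a4 lost its call in 11 of 36 fits that left out 1 library, and Slc30a5 without male IgG 6 or female IgG 7. Of 26 proliferation genes 0 passed in edgeR, over all genes or adjusted over the list alone (camera FDR = 0.435, fry adjusted p = 0.576). The smallest p-values were those of Tyms (−0.21, FDR = 0.111), Pcna (−0.18), Ccna2 (0.23) and Aurkb (0.30).

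Lists of other cell types were also called. Of 10 NK and cytotoxic genes 5 fell and 0 rose (6 and 0 adjusted over the list alone, camera FDR = 0.000669, adjusted p = 0.439 with an estimated correlation). The granzyme Gzma went from 16.2 ± 4.98 to 8.57 ± 2.00 CPM, Gzmk fell by 0.60, the chemokine Ccl5 by 0.56 and perforin (Prf1) by 0.50. Of 7 alveolar type II markers 3 fell and 0 rose (5 and 0 adjusted over the list alone, camera FDR = 0.00574, adjusted p = 0.439 with an estimated correlation). Sftpc and Sftpa1, which encode surfactant proteins, fell by 0.40 and 0.33, and the transcription factor Etv5 by 0.33. Sftpc stood at 18353 CPM in female normoxia 8 and 26219 CPM in female normoxia 9, against at most 12523 in the other 34 libraries, and without these libraries 1 of the type II markers fell. Of 8 platelet genes 4 fell and 0 rose (5 and 0 adjusted over the list alone, camera FDR = 0.0173, adjusted p = 0.439 with an estimated correlation). These were Clec1b (−0.93), Pf4 (−0.65), Treml1 (−1.13) and Nrgn (−0.50, not called in 14 of 36 fits that left out 1 library), and 1 fell without female normoxia 8 and 9. Of 12 adipocyte genes 4 rose and 0 fell (9 and 0 adjusted over the list alone, camera FDR = 0.0121, adjusted p = 0.589 with an estimated correlation). Among them the hormone-sensitive lipase Lipe rose in 12 of 12 libraries (103 ± 25.3 to 168 ± 27.1 CPM), whereas Cidea (1.37) and Plin1 (2.13) were higher in 7 of 12. Without male IgG 6 alone Cidea stood at 0.66 (FDR = 0.167, 0.00883 to 0.569 over the alternatives) and Plin1 at 0.96 (FDR = 0.366, 0.0133 to 0.839), and Plin1 lost its call in 24 of 36 fits that left out 1 library. Summed adipocyte CPM was 1116 in male IgG 6 and 613 in female IgG 11, and without those libraries and male APL-9796 5 the list was not called (FDR = 0.268, 0.0171 to 0.431 over 4 alternatives).

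**Figure D2:**
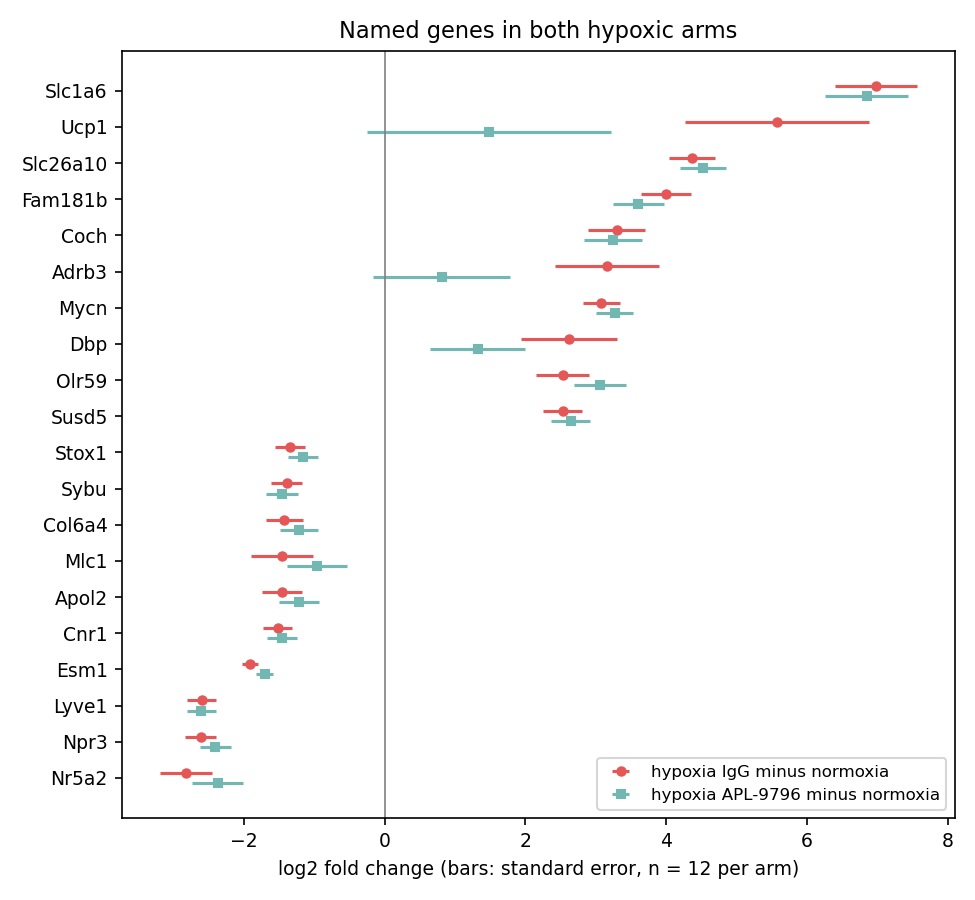
Log2 fold change against normoxia (horizontal axis, bars SE) of the 10 largest rises and the 10 largest falls of hypoxia with IgG, in the IgG arm (circles) and the APL-9796 arm (squares), 12 libraries per arm. Npr3 lies at −2.61 and −2.40 and Esm1 at −1.91 in the IgG arm, while Ucp1, Adrb3 and Dbp have the wide bars.

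The second question is what APL-9796 changed against IgG within hypoxia. No gene passed the threshold in edgeR (0 of 15570, 626 at an unadjusted p under 0.05, where 778 would be expected by chance, smallest FDR 0.967), and 0 passed with DESeq2 (764 unadjusted) or limma-voom (2417 unadjusted). Among genes that had moved with hypoxia, Npr3 stood at 18.5 ± 8.08 with IgG and 21.3 ± 7.83 CPM with APL-9796 (log2 difference 0.21, 95% interval −0.24 to 0.66), and Lyve1 stood at 69.8 ± 27.9 and 69.1 ± 24.6 (−0.00, −0.40 to 0.39). Edn1 differed by −0.07 (−0.35 to 0.22). The intervals for Col15a1 (−0.26 to 0.14), Emcn (−0.22 to 0.22) and Myl9 (−0.18 to 0.25) likewise held 0. Of the 68 genes named for hypoxia, 6 had an unadjusted interval that excluded 0, where 3.4 would be expected by chance, and 0 passed the threshold. These were Ucp1 (−6.43 to −1.75), Adrb3 (−2.35, −3.74 to −0.96), Cidea (−2.54 to −0.82), Plin1 (−3.38 to −0.48), Ccl5 (−0.55 to −0.04) and Kcnmb1 (0.01 to 0.46). The first 4 are fat cell genes, whose list had its highest summed CPM in male IgG 6 and female IgG 11, and both contrasts use the same IgG libraries. The interval of the median gene reached 0.207 log2 to either side. The 5 smallest p-values did not pass the threshold (FDR = 0.967 each). They belonged to the secreted airway protein Clca1 (rCG_28626, 28.2 ± 35.1 to 5.72 ± 3.15 CPM), the lipid droplet protein Cidea (9.04 ± 13.2 to 2.77 ± 1.38), the translation repressor Eif4ebp1 (log2 −0.33 ± 0.08), the lipogenic factor Thrsp (25.7 ± 47.4 to 3.94 ± 3.55) and Mid1 (log2 0.39 ± 0.11). Without male IgG 6, Cidea went from −1.68 to −0.96 and Thrsp from −2.74 to −1.62. With 6 libraries that stood apart left out, a setting chosen after seeing the data, 9 genes passed, all higher with APL-9796, among them Bcl9l (0.23), Zfhx3 (0.42), Ppp1r12b (0.31) and Hivep3 (0.46).

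By camera at the preset correlation, 12 lists differed between the hypoxic arms, but 0 did with an estimated correlation (adjusted p = 0.418 to 0.697) or with fry, and 0 of their genes passed over all genes. Lists higher with APL-9796 were smooth muscle contractile genes (camera FDR = 0.0120, adjusted p = 0.565 with an estimated correlation, Kcnmb1 0.23, Des 0.27, Lmod1 0.20). So were pan-endothelial markers (0.00667, adjusted p = 0.465, Erg 0.18, Ptprb 0.22, Eng 0.14) and BMP/TGF-beta genes (0.00731, adjusted p = 0.418, Bmpr2 0.20, Smad7 0.20, Inhba 0.67). General capillary markers (0.0245, adjusted p = 0.418, Cd93 0.16), vasoactive genes (0.0356, adjusted p = 0.418, Ednrb 0.15, Htr2b 0.38) and immediate early genes (0.00215, adjusted p = 0.666, Egr3 0.79, Nr4a2 0.24) were also higher. Summed immediate early CPM was 5871 in male APL-9796 6 and at most 2876 in the other males of that group, and without that library Egr3 stood at 0.38. Lists lower with APL-9796 were B cell markers (0.000164, adjusted p = 0.418, Ms4a1 −0.35, Cd79b −0.30) and T cell markers (0.00880, adjusted p = 0.565, Cd247, a chain of the T cell receptor complex, 7.58 ± 1.78 to 5.68 ± 1.41 CPM). NK genes (0.000586, adjusted p = 0.418, Xcl1 −0.62, Ccl5 −0.29) and club cell markers (0.0120, adjusted p = 0.494, Scgb3a1 −0.54) were lower as well. Adipocyte genes were lower (5.5e-06, adjusted p = 0.418, Ucp1 −4.09 and Cidec −1.24, or −2.26 and −0.55 without male IgG 6) and skeletal muscle genes higher (0.0432, adjusted p = 0.697, Acta1 2.04, Mybpc1 2.32). Summed skeletal muscle CPM was 3271 in male APL-9796 5 and at most 54.4 in the other males of that group, and without that library Acta1 stood at −0.05 and Mybpc1 at −0.62. Adjusted over the list alone, 9 adipocyte and 2 T cell genes were lower and 3 skeletal muscle genes higher. Without male IgG 6, female IgG 11 and male APL-9796 5, 7 of these lists were called, and the adipocyte list was not (FDR = 0.0593, 2.6e-05 to 0.273 over 4 alternatives). Calls were also lost in at least 1 of the 4 alternatives run for lists for pan-endothelial (FDR range 0.00558 to 0.311), capillary (0.0427 to 0.384), vasoactive (0.0158 to 0.259), T cell (0.00499 to 0.0740), club cell (0.00892 to 0.616) and skeletal muscle genes (0.0426 to 0.311).

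The other lists fixed for the question were not called by camera or fry with all libraries. HIF targets (FDR = 0.691) held Car12 at 0.86 (0.16 without male APL-9796 5), Ddit4 at −0.36, Pfkfb4 at 0.14 and Aldoc at −0.19. Zinc transporters (FDR = 0.691) held the metal-responsive factor Mtf1 at 0.12, Slc30a7 at 0.14, Slc39a2 at −0.07 and Slc30a4 at 0.05. Matrix genes (FDR = 0.208) held elastin (Eln) at 1279 ± 403 CPM with IgG and 1631 ± 532 with APL-9796, Thbs1 at 0.37 (0.12 without male APL-9796 6), Col12a1 at 0.18 and Fbn1 at 0.18. With 6 libraries left out, a setting chosen after seeing the data, the matrix list was called higher with APL-9796 (FDR = 6.3e-05, 6.3e-05 to 0.383 over 4 alternatives), but not with an estimated correlation (adjusted p = 0.859 in that setting). Proliferation genes (FDR = 0.201) held Tpx2 at 0.32, Melk at 0.32, Mcm5 at −0.23 and Aurkb at −0.29. In these 4 lists 0 genes passed in edgeR, over all genes or adjusted over the list alone.

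**Figure D3:**
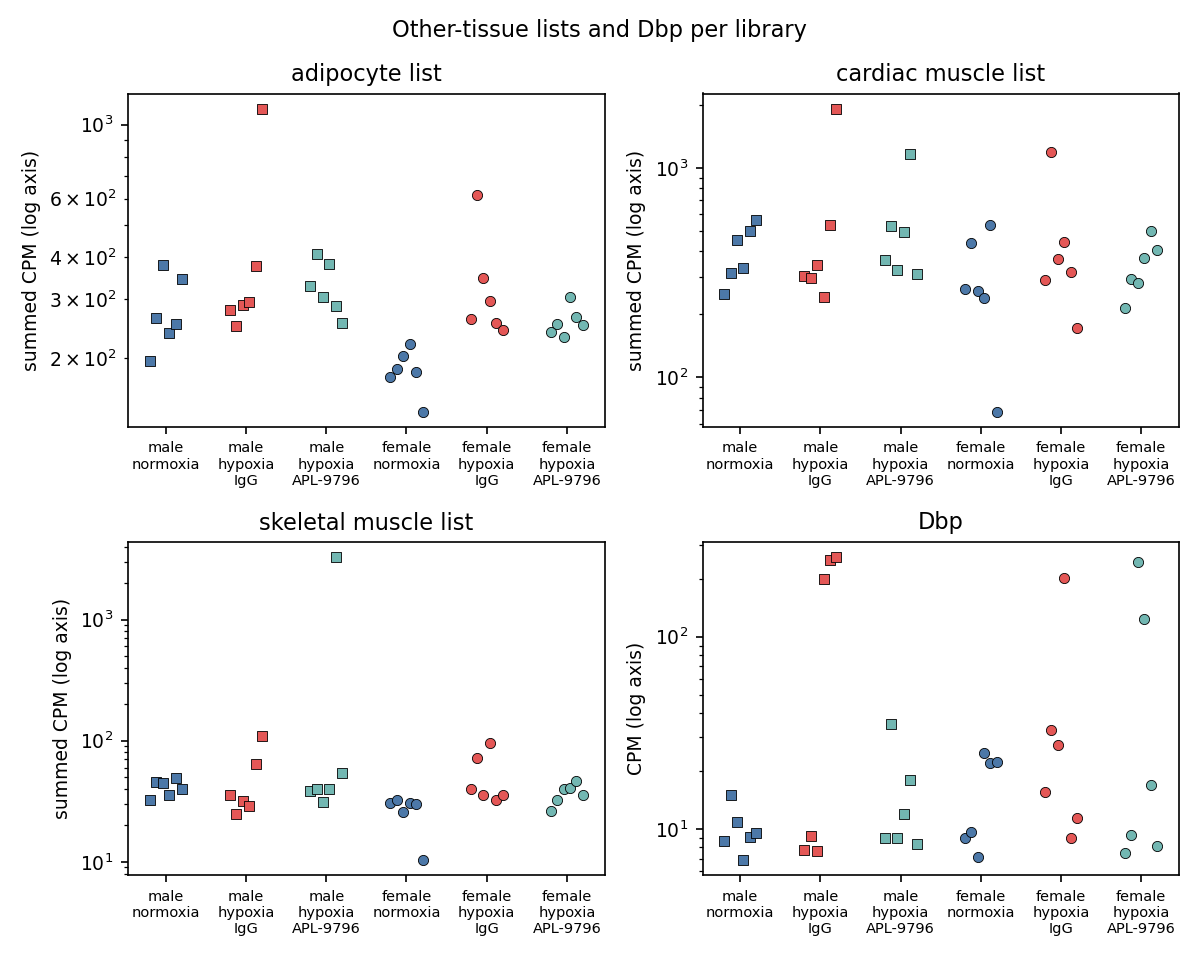
Summed CPM of lists of other tissues, and CPM of Dbp, in each of the 36 libraries (log axis), 1 point per library, by arm and sex. Adipocyte genes reach 1116 CPM in male IgG 6 and 613 in female IgG 11, and skeletal muscle genes 3271 CPM in male APL-9796 5.

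The third comparison set hypoxia with APL-9796 against normoxia. The sodium channel subunit Scn3b (rCG_58317) rose from 88.0 ± 20.2 to 452 ± 55.3 CPM (log2 2.36 ± 0.10, FDR = 6.9e-20), with 449 ± 42.3 CPM in the IgG arm. The growth factor genes Pdgfd and Pdgfb rose from 18.2 ± 2.53 to 53.7 ± 9.43 and from 114 ± 26.9 to 258 ± 35.7 CPM. The sodium channel Scn7a rose from 241 ± 69.4 to 924 ± 140 CPM and the phospholipase Plcb1 rose by 1.26. A total of 1413 genes were higher and 1391 lower, and 238 of these differed by more than 2-fold (186 higher, 52 lower). Slc1a6 had 364 counts in the APL-9796 libraries, a ratio to normoxia of 203 (exact 95% counting interval 55.7 to 1681).

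Matrix genes rose here too, 18 of 27 with 0 lower (20 and 0 adjusted over the list alone, camera FDR = 1.7e-13, adjusted p = 0.182 with an estimated correlation, 0.0177 to 0.221 over 4 alternatives). These included Eln, which went from 683 ± 307 to 1631 ± 532 CPM, Col15a1 (1.22) and the proteoglycan Bgn (0.49). Of 13 smooth muscle genes 9 rose and 0 fell (10 and 0 adjusted over the list alone, camera FDR = 2.6e-12), a call that held with an estimated correlation (adjusted p = 0.0486, 0.0392 to 0.139 over 4 alternatives). Cnn1 (1.04), Kcnmb1 (0.97), Des (0.97) and Myl9 (0.91) led. BMP/TGF-beta genes rose in 14 of 33 and fell in 3, also adjusted over the list alone (camera FDR = 0.00214, adjusted p = 0.195 with an estimated correlation). Members were Fst (1.52), the ligand gene Bmp2, Tgfbr2 (0.42) and Smad6 (−0.72). Of 17 endothelial markers 8 rose and 4 fell (11 and 4 adjusted over the list alone, camera FDR = 0.00127, adjusted p = 0.325 with an estimated correlation). These included Emcn (1.16), Robo4 (1.12), Mmrn2 (0.67) and Tek (−0.57). Pericyte and fibroblast markers gave 6 higher and 1 lower of 16, also adjusted over the list alone (camera FDR = 0.00170, adjusted p = 0.325 with an estimated correlation). Members were Ltbp2 (0.94), Gli1 (0.95), Notch3 (0.91) and Kcnj8 (0.44).

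NK genes fell in 8 of 10, and 10 of 10 adjusted over the list alone (camera FDR = 5.5e-07, adjusted p = 0.195 with an estimated correlation). These included Gzma (−0.95), Ccl5 (−0.85), Gzmk (−0.77) and Nkg7 (−0.64). Type II markers fell in 5 of 7, also adjusted over the list alone (camera FDR = 0.00214, adjusted p = 0.197 with an estimated correlation). These included Sftpc (−0.51), Sftpa1 (−0.39), Etv5 (−0.32) and Napsa (−0.26). Without female normoxia 8 and 9 the count was 4. Glycolysis genes gave 4 higher and 1 lower of 15 (6 and 1 adjusted over the list alone, camera FDR = 0.0433, adjusted p = 0.660 with an estimated correlation). Members were Aldoc (0.93), Pfkl (0.56) and Pdk4 (−0.88, not called in 6 of 36 fits that left out 1 library). The list was not called without the 3 libraries named for Ucp1 (FDR = 0.124, 0.00619 to 0.124 over 4 alternatives). HIF targets (camera FDR = 0.424, fry adjusted p = 0.0923, 1.0e-07 for changes in either direction) gave 3 higher and 1 lower of 19, 3 and 2 adjusted over the list alone, among them Pfkfb4 (0.42), Pdk1 (0.34) and Angptl4 (−0.61), with a median of 0.08 and a mean of −0.00. Zinc transporters (camera FDR = 0.424, called lower by fry with adjusted p = 0.0287) gave 0 higher and 3 lower of 17, also adjusted over the list alone: Slc30a5 (−0.23), Slc39a4 (−0.23) and Slc30a6 (−0.24), with 1 higher and 1 lower without female normoxia 8 and 9. Leaving out 1 library ended the call of Slc39a4 in 18 and of Slc30a6 in 26 of 36 fits. Vasoactive genes (camera FDR = 1, fry adjusted p = 0.926, 2.2e-21 for changes in either direction) gave 7 higher and 6 lower of 26, 11 and 7 adjusted over the list alone, with Npr3 (−2.40), Edn1 (−1.34), Apln (−0.76) and the cation channel Trpc6 (0.83). Of 26 proliferation genes (camera FDR = 0.268, fry adjusted p = 0.305) the replication clamp Pcna fell by 0.25 (not called in 14 of 36 fits that left out 1 library), and 0 passed adjusted over the list alone.

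The fourth question is how the APL-9796 effect relates to the hypoxia effect. When the IgG libraries were divided between the contrasts, so that they shared none, the correlation across genes of the log2 changes had a median of 0.107 (range −0.109 to 0.226 over 50 divisions, covariance 0.00782), and 45.1% of genes moved in opposite directions. Among genes called for hypoxia the median correlation was 0.110 (−0.327 to 0.522 over the divisions), with 38.8% opposite (27.8% to 53.4%). Simulated libraries that kept the hypoxia effect gave 0.00689 (−0.0168 to 0.0623 over 10 draws) with none of it undone by APL-9796, and −0.249 (−0.280 to −0.215) with 25% undone. Simulated genes varied independently and no simulated library stood apart. These ranges may therefore be too narrow for the real libraries and do not by themselves exclude a partial move back. With shared IgG libraries the correlation was −0.134 and the covariance −0.00831, against −0.494 and −0.0122 in simulated libraries with no change in either contrast. Within males the divided correlation over all genes was 0.0877 and within females 0.0192. Among genes called for hypoxia it was −0.00845 within males and −0.0243 within females. Genes are not independent replicates. Between the contrasts of each hypoxic arm with the shared normoxic libraries the correlation was 0.852 (simulated unchanged 0.490, covariance 0.10 against 0.0120) and with divided normoxic libraries 0.690. Both arms called 886 genes higher and 693 lower, and 0 in opposite directions, where independent lists would share 89.2 and 86.1 and simulated unchanged groups shared 0. Because both contrasts use the same normoxic libraries, the overlap was also counted with these divided, which gave medians of 459 higher and 206.5 lower, against 42.3 and 26.7 for independent lists.

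By sex, hypoxia with IgG raised 293 and lowered 190 genes in males, and raised 1125 and lowered 1288 in females (n = 6 per group). Scn3b (2.26 in males, 2.45 in females), Scn7a (1.85 and 1.97) and Esm1 (−1.67 and −2.15) were among the smallest p-values in both sexes, joined by Pdgfd (1.66) and Slc26a10 (4.12) in males and Pdgfb (1.33) and Col15a1 (1.58) in females. A model of the compared groups alone called 781 genes in males and 610 in females. The test of the difference between the sexes called 2 genes. Osteopontin (Spp1, rCG_37885) went from 4.59 ± 2.10 to 22.2 ± 12.6 CPM in males and from 6.47 ± 2.08 to 5.01 ± 1.02 CPM in females (difference −2.64 ± 0.49, FDR = 0.0399). The unnamed gene rCG_27691 went from 65.8 ± 16.7 to 43.6 ± 4.64 and from 42.3 ± 4.86 to 72.5 ± 14.2 CPM (1.37 ± 0.24, FDR = 0.0395). With all libraries, 2480 genes had an unadjusted p under 0.05 for this difference in edgeR, where 778 would be expected by chance. Also with all libraries, 55 genes passed the threshold with DESeq2 and 431 with limma-voom. Without female normoxia 8 and 9, the hypoxia count fell to 968 in females and rose to 754 in males, whose own libraries were unchanged. The difference between the sexes then called 0 genes in edgeR.

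APL-9796 against IgG called 0 genes in males (edgeR, 597 at an unadjusted p under 0.05, 0 with DESeq2 or limma-voom) and 0 in females (786 unadjusted, 0 with DESeq2, 6 with limma-voom). In males the smallest p-values were those of the keratin Krt4 (7.98, FDR = 0.0798), Ada (3.66), the muscle calcium pump Atp2a1 (6.79), Il1rl2 (0.69) and the muscle myosin chain Myl1 (6.29). Krt4 stood at 1674 CPM in male APL-9796 5 and at most 1.49 in the other males of that group. In females they were the kinase Fer (0.41), Mid1 (0.69, FDR = 0.418), Kcnh1 (0.83), Hipk2 (0.70) and Acot7 (−0.34). The 6 limma-voom genes in females were Hipk2, Hivep3, Fer, Smyd4 and 2 without a name, all higher. Sequencing run B held 4 of 6 female IgG libraries and 1 of 6 female APL-9796 libraries, so antibody and run are partly mixed in females. The difference between the sexes called 0 genes (edgeR, 685 unadjusted, 0 with DESeq2 or limma-voom), with Atp2a1 (−8.75), Il1rl2 (−0.77), Actg2 (−0.88), Ada (−3.80) and Fer (0.45) at the smallest p-values (FDR = 0.963).

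Between the sexes in normoxia, 864 genes were higher and 788 lower in females. The translation factor gene Eif2s3 stood at 86.0 ± 6.81 CPM in males and 196 ± 51.5 in females (1.19 ± 0.10, FDR = 4.4e-10, n = 6 each). The focal adhesion protein Zyx stood at 383 ± 66.0 and 220 ± 51.2 CPM, and the ephrin receptor Ephb1 at 8.39 ± 2.59 and 2.66 ± 0.998 CPM. Pbdc1 (0.94) was higher and the retinoic acid enzyme Aldh1a3 (−0.84) lower in females. Without female normoxia 8 and 9 the total of 1652 was 25. With the compared groups alone it was 4, among them Eif2s3 and Aldh1a3, and Zyx, Ephb1 and Pbdc1 did not pass.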

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

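All tests of explanations in this part, the counts over other splits of the samples and the choice of Krt4, Acta1 and S100a8 were made after the results were seen; the tests between the sexes were planned. Dixon's test of the highest and lowest library (95% critical value 0.625 for 6) was applied to 34 measures in 6 groups. It marked 34 of 204 groups, where chance marks about 1 in 20 for separate, normally distributed measures. The measures here were largely CPM, some near 0, and some overlap, so the excess of marks is not a measured rate. Marked levels of Krt4 in female IgG 7, of Adrb3 in female normoxia 12 and of Slc1a6 lie below the 3-count limit of their libraries.

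Several libraries held high levels of genes of other tissues. Adipocyte genes summed to 1116 CPM in male IgG 6 (nearest library of the group 376) and 613 in female IgG 11 (347). Cardiac muscle genes summed to 1922 CPM in male IgG 6 (536), 1193 in female IgG 11 (444) and 1166 in male APL-9796 5 (531). Skeletal muscle genes summed to 3271 CPM in male APL-9796 5 (54.4), with the actin Acta1 at 1267 (30.1) and the epithelial keratin Krt4 at 1674 (1.49), and to 10.3 in female normoxia 9 (25.7). Krt4 stood at 0.106 CPM in female IgG 7 (1.38). Ucp1 stood at 113 CPM in male IgG 6 (7.44), 76.1 in female IgG 11 (16.3), 12.3 in male APL-9796 2 (0.331) and 4.97 in female APL-9796 7 (0.126). Adrb3 stood at 11.6 CPM in male IgG 6 (1.89), 5.46 in female IgG 11 (1.88), 3.12 in male APL-9796 2 (1.19) and 0.304 in female normoxia 12 (0.114).

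Other marked levels concerned genes named for hypoxia. In female IgG 7, Dbp stood at 202 CPM (32.8), summed clock genes at 1497 (880), Coch at 8.02 (3.43) and Slc26a10 at 31.4 (20.3). Dbp stood at 35.2 CPM in male APL-9796 2 (17.9), Mycn at 30.9 in female APL-9796 8 (10.8), Susd5 at 8.12 in male IgG 6 (5.67) and Apol2 at 4.25 in male IgG 5 (1.74). Fam181b stood at 0.947 CPM in female normoxia 10 (0.171), and Slc1a6 at 0.0965 in male normoxia 3 and 0.0531 in female normoxia 9, where the other libraries of their groups had 0. Immediate early genes summed to 5871 CPM in male APL-9796 6 (2876). The neutrophil gene S100a8 stood at 45.7 CPM in male APL-9796 4 (16.8) and 5.7 in male IgG 3 (8.16). A hypoxia score described among the other observations stood at 67.6 in male IgG 5 (94.3) and 124 in female IgG 7 (101). The planned test between the sexes marked Spp1 (−2.64) and rCG_27691 (1.37).

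Hypoxia called 5.0 times as many genes in females as in males. Without female normoxia 8 and 9, in which 8.28% and 10.7% of counts fell on 10 genes, the ratio was 1.28, with the female count down from 2413 to 968 and the male count up from 483 to 754. In a model of the compared groups alone, which kept both libraries, it was 0.781 (610 against 781 genes), so these libraries may act in part through the spread that the model shares among groups. The sequencing run cannot be told apart as a source: with run as a term the ratio was 3.26, and in run A alone 0.187, where females kept 2 IgG and 3 normoxic libraries. A difference of response between the sexes stays open as well, because the direct test in edgeR called 2 genes with all libraries and 0 without both. With all libraries, DESeq2 and limma-voom called more genes for this difference than edgeR did.

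The rise of Ucp1 and of other adipocyte genes with hypoxia stood out because it was uneven between libraries. In female IgG 11 the median of 9 other adipocyte genes lay 2.29 log2 above the median of the other libraries, and in male IgG 6 it lay 3.76 above, with 7 of 9 over 2-fold in each. These libraries were picked by the same list, so the values restate the pattern, and fat tissue carried along stays open. Against a response in each animal, Ucp1 exceeded the highest normoxic library in 6 of 24 hypoxic libraries. Of the 12 adipocyte genes tested, 10 had 1 CPM or more in normoxia, and whether hypoxia changed the fat attached to the tissue was not tested.

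The rise of Dbp may reflect the time of day at which tissue was taken, which the labels do not give. Group means were removed from log2 CPM, which was then averaged over 7 genes in phase with Dbp and over 4 in phase with Bmal1. Over the 36 libraries the 2 averages were inversely related (r = −0.952, rho = −0.903, permutation p = 1e-05 each, the smallest 100000 resamples can give). Without the 2 farthest libraries r was −0.938. The relation held in run A (r = −0.957, 26 libraries), run B (−0.976, 9 libraries) and within normoxia (−0.768), IgG (−0.984) and APL-9796 (−0.946). Dbp exceeded the normoxic median of its sex in 12 of 24 hypoxic libraries, which argues against a rise in each animal. Genes of the 2 phases move oppositely in any shift of the clock, and removing group means takes out the difference between arms. The relation therefore cannot tell time of day from an effect of hypoxia on the clock in some animals. Dbp stood at 198.6 to 259.6 CPM in male IgG 4, 5 and 6 and at 202 in female IgG 7. It stood at 124 and 246 CPM in female APL-9796 7 and 12, and at most 24.85 in normoxia.

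Other splits of the same samples into groups of the same sizes were refitted, 100 per contrast with the real one included. Where the real split alone was as large, its share was 1 in 100, the smallest these splits can give. That was so for hypoxia (1947 genes, highest other 64), hypoxia in males (483, 1) and APL-9796 against normoxia (2804, 534). It was also so for hypoxia in females (2413, 1783) and sex in normoxia (1652, 803). In these contrasts 14 and 11 of 99 other splits gave calls. For the difference of the hypoxia effect between the sexes, 3 splits were as large (real 2; highest other 14), a share under 0.05 that rests on 2 genes. A real count of 0 makes each of the 100 splits as large by construction, which says nothing about chance. This held for APL-9796 against IgG (highest other 8), in males (47), in females (0) and for the difference between the sexes (13). The highest other splits had more calls than the real one for the difference of the hypoxia effect (14 against 2) and for APL-9796 in males (47 against 0). The median other split had 0, and 4 and 14 of 99 had any call. Whether the samples hold a structure beside the groups was not tested.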

How the results depend on the processing

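The run term, run A alone and the settings with 2, 3 or 6 libraries left out were chosen after the data were seen, the others before. The cause of each shift below was not tested, except that glmTreat, with its stricter null, calls fewer genes by construction. Counts of genes for hypoxia (1947) and for APL-9796 against normoxia (2804) stayed within 1.5-fold (1480 with 1 surrogate variable to 2554 with limma-voom, and 1904 to 3842) except with glmTreat (485 and 609) and, for hypoxia, run A alone (725). Leaving out each library in turn gave 1523 (without female IgG 7) to 2298 (without female normoxia 7) for hypoxia, 0 to 0 for APL-9796 against IgG, and 2260 (without male normoxia 3) to 3633 (without female normoxia 7) for APL-9796 against normoxia. APL-9796 against IgG gave 0 in each planned setting (edgeR 626, DESeq2 764 and limma-voom 2417 at an unadjusted p under 0.05) and 9 with 6 libraries left out; in females it gave 6 with limma-voom. In males hypoxia (483) gave 1066 with limma-voom, 781 with the compared groups alone, 754 without female normoxia 8 and 9, and 1113 with 6 left out. In females (2413) it gave 610 with the compared groups alone, 1607 with the run term, 99 in run A, 968 without female normoxia 8 and 9, and 1147 with 6 left out. The difference between the sexes (2) gave 55 with DESeq2, 431 with limma-voom, 1 with the replicate block, and 0 with no filter, with the run term, in run A and with 2, 3 or 6 libraries left out. Sex in normoxia (1652) gave 4 with the compared groups alone, 808 with the run term, 39 in run A, 25 without female normoxia 8 and 9, and 158 with 6 left out. Camera called 10, 12 and 8 lists for hypoxia, APL-9796 against IgG and APL-9796 against normoxia; an estimated correlation left 0, 0 and 1, fry called 18, 0 and 13 by direction, and fry mixed 15, 0 and 19. For APL-9796 against IgG, 7 lists were called without the 3 libraries high in genes of other tissues. With shared IgG libraries the relation of the APL-9796 and hypoxia effects was −0.134 in place of 0.107. Of the named genes past the threshold, 43 of 68 for hypoxia and 40 of 46 for APL-9796 against normoxia kept their call in each setting tested, and 0 reversed; Plin1 lost it in 10 settings, Mlc1 and Cidea in 8, Slc39a4 and Pfkfb4 in 7 and Slc30a5 in 6. Replicate numbers 1 to 12 are shared by the arms, but the labels do not say what a number marks: same-numbered libraries deviated together with r of −0.197 to 0.300 (median 0.0138; 8 of 36 pairs over 0.1), and 14 of 72 best matches had the same number. With the replicate block, hypoxia gave 1808 genes, APL-9796 against normoxia 2606, APL-9796 against IgG 0, and hypoxia in males 438 and females 2189; the sex contrast could not be fitted with it. RLE size factors moved the median change by at most 0.0103. Leaving out haemoglobin genes, a planned setting, was not run because 0 genes carried such a symbol. In simulated data, 50% and 86% of 1.5- and 2-fold changes were recovered for APL-9796 in males and 63.5% and 83% in females, so smaller changes within a sex were below what this depth and number of libraries resolve in most genes.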

Other observations

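The hypoxia score, its tests and the genes named here beyond the rule were chosen after the data were seen; the list tests were planned.

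Lymphatic endothelial markers parted in hypoxia with IgG: 4 of 6 rose and 1 fell, also adjusted over the list alone, and the list was not called by camera (FDR = 0.347) but was by fry (adjusted p = 0.0125). The lymphatic chemokine Ccl21 went from 107 ± 18.3 to 187 ± 52.0 CPM, the lymphatic transcription factor Prox1 rose by 0.90 (FDR = 0.00138), Reln by 0.68 (FDR = 0.00445) and Tbx1 by 0.49 (FDR = 0.00395), whereas Lyve1, which some macrophages also express, fell by 2.60. Of 9 genes of the carbonic anhydrase family, 1 rose and 2 fell. Car11 went from 8.23 ± 2.07 to 11.9 ± 3.11 CPM, Car8 from 182 ± 34.2 to 147 ± 16.4 and Car5b from 43.1 ± 15.6 to 33.1 ± 2.68 CPM. Of 14 interferon-stimulated genes 3 rose and 0 fell: Irf7 (0.58), Usp18 (0.53) and Cxcl10 (0.60).

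Each list of capillary and vessel-type endothelial markers held genes that rose and genes that fell, and the lists were not compared with each other. Of 8 aerocyte markers 1 rose and 2 fell, of 8 general capillary markers 1 rose and 2 fell, and of 14 arterial and venous markers 3 rose and 4 fell. Of 14 clock genes 2 rose and 1 fell: besides Dbp, Cry2 rose by 0.62 (FDR = 0.000525) and Clock fell by 0.27 (FDR = 0.0382). Among lists of airway and alveolar cells, 2 of 12 type I markers fell, 2 of 7 club cell markers rose and 1 fell, and 0 of 9 ciliated markers passed. Among immune lists, 2 of 12 interstitial macrophage markers fell, 1 of 9 alveolar macrophage markers rose, 1 of 14 T cell markers rose, and 0 of 11 B cell markers passed. In the edgeR test of hypoxia 0 of 14 cardiac, 0 of 7 skeletal muscle and 0 of 7 mesothelial genes passed.

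A hypothesis that APL-9796 moved the lungs back toward normoxia was tested with a hypoxia score per library. The score weighed 1502 genes higher and 1741 lower in the mean of both hypoxic arms, in percent of the distance between normoxia and the mean of the hypoxic arms. It averaged 95.3 ± 12.8 with IgG and 105 ± 20.2 with APL-9796 (SD, n = 12 each), a difference of 9.49 (95% bootstrap interval −3.63 to 22; permutation p = 0.196, two-sided). For the genes in the score, the interval excludes a move back by 25. It cannot exclude one in other genes. The score genes were chosen in these same libraries, where a gene returned to normoxia by APL-9796 is harder to choose. The bootstrap kept genes and scale fixed. Female normoxia, which helps set the scale, had an SD of 39.5, with female normoxia 9 at −71.4. The difference was 14.5 in males, 4.47 in females, 10.2 in run A and 11.7 without the 3 libraries high in genes of other tissues. A smaller move back in single genes, or 1 in tissue properties that RNA does not show, may remain, as may an excess over IgG.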
